A study of Mus musculus with 5 samples.

How the data were processed

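The samples were 5 single-cell RNA libraries of CD4-sorted cells from the central nervous system of mice with experimental autoimmune encephalomyelitis, 2 from Foxp3-YFP-Cre mice (control) and 3 from Foxp3-YFP-Cre Notch3 fl/fl mice (cKO). Per the submitters' processing notes, reads from 10x 3′ libraries (chemistry version 3.1) were aligned and counted with Cell Ranger 7.1.0 against the mm10 genome. The deposited matrices hold raw UMI counts per gene and cell barcode, and the cell barcodes had been chosen by that pipeline. Group, replicate number and tissue were taken from the labels, which do not state sex, animal or day.

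Cells with at least 500 genes and under 10% mitochondrial UMIs were kept, with 200 genes as a loose and 1000 genes and 5% as a strict alternative. Doublets were scored with Scrublet in scanpy 1.11.5, whose automatic threshold marked 1 barcode in all, so the highest-scoring share was removed at 0.8% per 1000 barcodes, that is, 64 and 90 barcodes in controls 1 and 2 and 108, 255 and 247 in cKO 1, 2 and 3. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components and 15 neighbours without antigen receptor segments, ribosomal, mitochondrial and sex-linked genes, entered Leiden clustering at resolution 1, with 0.5 and 2 as alternatives (Python 3.11.15, anndata 0.12.19, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9, umap-learn 0.5.12, matplotlib 3.10.9; seed 1).

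Each cluster was named from marker lists fixed in advance. A cluster was T-like with Cd3e in at least 60% of its cells and was set apart as Cd8a-bearing with Cd8a in at least 50%. A marker counted as raised at 1.5-fold over other cells, with a pseudocount of 10 CPM and a UMI in at least 10% of the cluster. A T-cell name needed at least 3 raised markers and no other list with more members among the 10 leading genes, which needed a UMI in at least 20% of the cluster. Clusters outside the T cells needed 3 of their markers among those genes. Clusters that met no rule stayed unnamed, and a non-T cluster whose depth was under 0.5 of its library medians was called shallow. The T-like total holds the Treg-like, conventional, cycling and unnamed T-like clusters, and leaves out the innate-like, Cd8a-bearing and mixture clusters. Shares per library were compared by exact two-sided permutation over the 10 splits of the libraries, where 0.1 is the smallest possible p, with Benjamini-Hochberg adjustment, and cell numbers were also tested with edgeR. Wilson intervals of 95% are given for shares, and a count of 0 is given with the share or level that 3 counts would make. These intervals and limits cover counting error only.

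Counts were summed per library over Treg-like, conventional CD4 T-like and all T-like cells, and over every other cluster with at least 20 cells in each library, so that libraries are the replicates. Genes were tested with the quasi-likelihood method of edgeR 4.0.16 in R 4.3.3 after its default low-count filter and TMM scaling, two-sided, with genes called at a Benjamini-Hochberg adjusted p under 0.05. The difference of the genotype effects between the classes was fitted with library terms. DESeq2 1.42.0, RLE scaling, no filter, a replicate block, equal cells and UMIs, other filters and resolutions, and leaving out each library were alternatives. Lists of genes, 28 in all, were tested with camera on voom values in limma 3.58.1 with a preset correlation of 0.01, and again with an estimated correlation and with fry. In the difference of effects the estimated correlation depends on rounding in the weighted fits, and its adjusted p is read only as passing or not. A list was tested with at least 3 measured members.

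For the share of cells with a UMI of a gene, cells were thinned to 2000 UMIs, shallower cells being left out, and dendritic-like cells were the reference for background. The genes named in the text are the 26 panel genes, fixed in advance, and the 10 with the smallest p in each comparison. A few genes chosen by these rules are not reported here. For the comparison of cells by sex they are up to 10 in each direction by fold, called, autosomal, with a mean of at least 20 CPM and the same direction in all 3 libraries, without predicted genes and receptor segments. Up to 4 members are named per list. Gene positions came from GENCODE vM21 on mm10, found for 99.8% of features.

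The samples, the main analysis, the panel, the lists, the markers and the alternatives not named in the next sentence were chosen before the data were examined. Covariates for the library pairs and for the number 1 libraries, the libraries with both sexes of cells alone, cells with Xist alone, and leaving out single clusters were added after. Cells were called Y-bearing by UMIs of 4 Y-linked genes without Xist, and Xist-bearing by Xist without those, and between 3000 and 8000 UMIs they were compared within the 3 libraries that held both. The fits were tested on counts simulated at the gene means and estimated spread of these libraries, without their shared structure. In each of 5 runs 200 genes with a mean of at least 20 CPM were changed. At 1.5-fold edgeR recovered 32.2% of changed genes in Treg-like, 28.4% in conventional and 35.2% in all T-like cells, and at 2-fold 93.1%, 93.1% and 93.4%, with 7.4, 9.2 and 5.4 false calls per run. Checks of the deleted exons were left out, since the count matrices hold no reads.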

Results

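The data were single-cell RNA counts of CD4-sorted cells from the central nervous system of mice with experimental autoimmune encephalomyelitis, an induced autoimmune disease of the brain and spinal cord used as a model of multiple sclerosis. The 2 control libraries came from Foxp3-YFP-Cre mice, which make Cre recombinase and a yellow fluorescent protein in cells that express Foxp3, the lineage factor of regulatory T cells (Tregs). The 3 cKO (conditional knockout) libraries came from Foxp3-YFP-Cre Notch3 fl/fl mice, in which that Cre deletes a loxP-flanked part of Notch3, a receptor of the Notch family, in Tregs. The labels name the cell type as Treg while the sort was on CD4, and the libraries held Treg-like and other T cells. The comparisons ask what losing Notch3 in Tregs changed in these cells and in the T cells around them.

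Control libraries 1 and 2 held 2820 and 3352 cell barcodes with 13534556 and 13991495 UMIs (unique molecular identifiers) in all. The cKO libraries 1, 2 and 3 held 3673, 5650 and 5563 barcodes with 21216595, 25072941 and 30780495 UMIs. Median UMIs per barcode ran from 3668 in cKO library 2 to 4598 in cKO library 1. After filters 20026 cells remained, of which 18972 lay in Treg-like, conventional CD4, cycling and unnamed T-like clusters, together called T-like cells here. The 193 innate-like T-like cells and the 253 cells of a mixture with macrophage genes, whose clusters also carried Cd3e, are not counted among them or in the Treg-like share. Values per group below are means ± SD over libraries, with n = 2 controls and n = 3 cKO. The labels do not say that each library is a separate animal, so the p-values measure the spread between these samples, part of which may be technical.

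Treg-like cells, 6665 in all, fell into 4 clusters. Cluster 5 was led by Tnfrsf9, Klrg1, Gzmb, Il1rl1, Il2ra and Foxp3, genes of activated and tissue Tregs, and cluster 8 by Hdac9, St8sia6, Ikzf2 and Ikzf4, the last pair encoding the zinc-finger factors Helios and Eos. Cluster 12 was led by Gbp2b, Iigp1 and Socs2, and cluster 10 held 931 cells with a median of 10240 UMIs. Conventional CD4 T-like cells, 9167 in all, fell into 6 clusters. Cluster 1 carried Ly6c2, Ccl5, Nkg7, Tbx21 and Cxcr3, genes of Th1 cells, and cluster 6 carried Il23r, Il1r1 and Ccr6, genes of Th17 cells. Cluster 3 carried Ccr7, Igfbp4, Dapl1 and Bach2 of naive and memory cells, cluster 9 the activation genes Ccl1, Ifng, Nr4a3 and Egr2, cluster 0 Tcf7 and Il6ra, and cluster 7, with 0.804 of its library medians in UMIs, had Rflnb, Tcf7, Nsg2, Cmss1, Gm42418 and Lars2 among its leading genes. Cluster 7 made up 1.74% and 4.48% of kept cells in cKO 1 and control 1. It was 6.37%, 10.7% and 13.1% in control 2, cKO 3 and cKO 2, the library order of the Gm42418 levels given below. Smaller classes were cycling T-like cells, innate-like T-like cells with Zbtb16 and Tcrg-C4, a mixture of T cells with macrophage genes such as Apoe and C1qa, dendritic-like cells with Siglech and Tcf4, and a shallow class led by Gm29114 and Il27.

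The Treg-like share of T-like cells was 36.3% ± 1.89 (SD, n = 2) in controls and 34.6% ± 0.981 (SD, n = 3) in cKO libraries, a difference of -1.66 percentage points (two-sided exact permutation p = 0.3). With 2 against 3 libraries the 10 possible splits can give no p below 0.1. Per library the share was 37.6% and 34.9% in controls 1 and 2 and 33.8%, 35.7% and 34.3% in cKO 1, 2 and 3, and the Wilson 95% interval of cKO 2 was 34.4% to 37.1%. Without control library 1 the difference was -0.323 points, and without control library 2 it was -3.0 points. The strict cell filter gave -2.18 points (two-sided exact permutation p = 0.1), and resolutions 0.5 and 2 gave -2.48 and -3.27 points (each with an exact permutation p = 0.2), all 3 with the groups fully apart. The loose cell filter gave -0.949 points at shares of 22.97% and 22.02% (exact permutation p = 0.9) and keeping doublets -1.41 points (exact permutation p = 0.3), neither with the groups apart. Calling Tregs by a Foxp3 UMI alone turned its sign, at 0.565 points.

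No class of cells was fully apart between genotypes. Among all kept cells, Treg-like cells made up 33.5% ± 3.66 (SD, n = 2) of control and 33.3% ± 0.314 (SD, n = 3) of cKO libraries, and conventional CD4 T-like cells 44.2% ± 0.759 and 46.8% ± 3.04. Cycling T-like cells were 2.32% ± 0.544 and 2.37% ± 0.717, unnamed T-like clusters 12.2% ± 1.42 and 13.7% ± 1.51, and innate-like T-like cells 1.06% ± 0.565 and 0.917% ± 0.174. The macrophage mixture was 1.09% ± 0.162 and 1.32% ± 0.316, dendritic-like cells 0.559% ± 0.275 and 0.460% ± 0.0818, and the shallow class 4.74% ± 6.39 and 0.837% ± 0.942, with 0.219% in control 1 and 9.26% in control 2, which held 295 of its 432 cells. Chance parts the groups fully in 20% of cases (2 of 10 splits), and 0 of 9 classes were parted, each with a Benjamini-Hochberg adjusted exact permutation p of 1. Tests of cell numbers in edgeR called 0 classes too, with 0 at an unadjusted p under 0.05 and an adjusted p of 0.952 for each class among all kept cells and of 0.878 for each T-like class, the innate-like one included, among those classes alone. Leaving out 1 library parted 7 classes without control 1, 3 without control 2, and 1 each without cKO 1 and cKO 2. With 1 control left chance parts the groups in 2 of 4 splits. Without control 1 every control share also rests on control 2, with its shallow class of 9.26%.

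**Figure D1:**
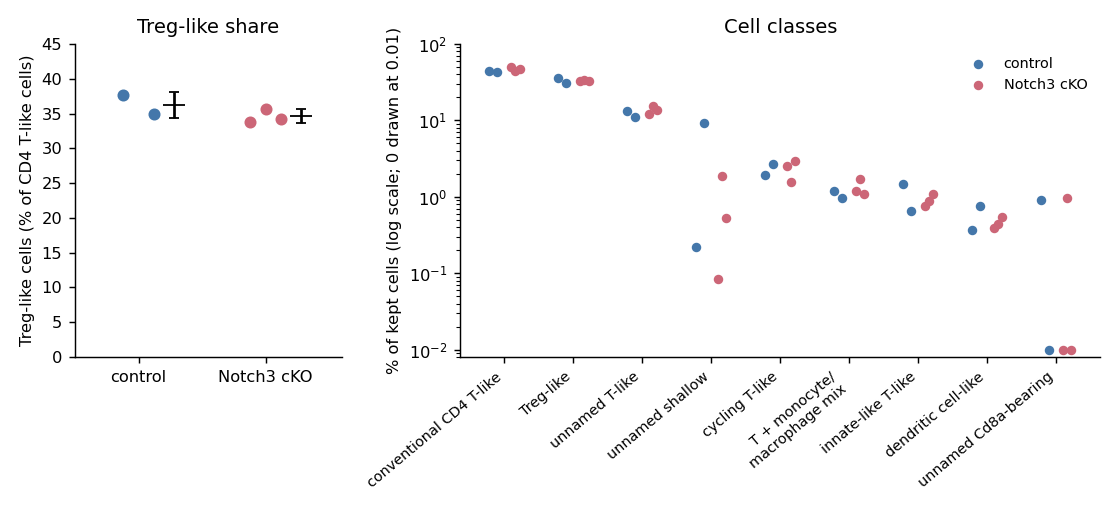
Treg-like percent of T-like cells with the group mean and SD (left), and percent of kept cells in each class on a log axis with 0 drawn at 0.01 (right), points for the 2 control and 3 cKO libraries. Among kept cells the Treg-like share lay between 30.9% and 36.0% in every library, and the groups overlapped in all classes.

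Notch3 itself (ENSMUSG00000038146; mm10, chromosome 17, 32120820 to 32166852, a protein-coding gene) was at the limit of detection. In all kept cells of control libraries 1 and 2 it had 2 and 1 UMIs, and in cKO libraries 1, 2 and 3 it had 2, 4 and 4, together 13 UMIs in 12 of 20026 cells. In Treg-like cells the controls had 0 UMIs each and the cKO libraries 1, 1 and 0. A count of 0 allows up to 0.584 and 0.686 CPM (counts per 1000000 UMIs) in Treg-like cells of controls 1 and 2, that is, a Notch3 UMI in up to 0.303% and 0.305% of the cells. The level was too low to test, and a loss of Notch3 was not detectable at this depth. The tag at the gene's 3′ end can also lie outside the loxP-flanked part, so these counts do not check the deletion.

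The libraries differed from each other in ways that the genotype does not explain. In control 1 and cKO 2, cells with Xist, the X-inactivation RNA of female cells, and no Y-linked UMIs were 77.6% and 74.2%, and cells with Y-linked UMIs alone 0.984% and 0.985%, against 33.6% to 37.0% in the other 3. This pair also had far more Gdpd3 (114.7 and 92.7 CPM in T-like cells, against 2.56 to 4.0) and Pde4d, a cAMP phosphodiesterase (1080 and 1006 CPM, against 103 to 139). With genotype as a covariate, 49 genes in Treg-like cells and 78 in conventional cells separated this pair from the rest in edgeR. The pair was picked by its Xist and Y-linked UMIs, and 42 and 71 of these genes were autosomal. Independently, control 1 and cKO 1 had low counts of Gm42418 and AY036118, which overlap ribosomal RNA repeats, and of Lars2. Gm42418 was 2760 and 1153 CPM there, against 7763, 44454 and 35922 CPM in control 2, cKO 2 and cKO 3. In Treg-like cells 36 genes passed the test of this contrast, 35 of them lower in control 1 and cKO 1, among them Cmss1 and Cdk8, while Gm42418, AY036118 and Lars2 did not pass (adjusted p = 0.226, 0.138 and 0.0968). Both contrasts cross the genotypes. Of the 9 other splits of the libraries, the 1 by this pair called the most genes, 57 in Treg-like and 75 in conventional cells, against 0 by genotype, sex-linked genes included, which points to a structure of the libraries. The 10 splits are too few for a share under 0.05.

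**Figure D2:**
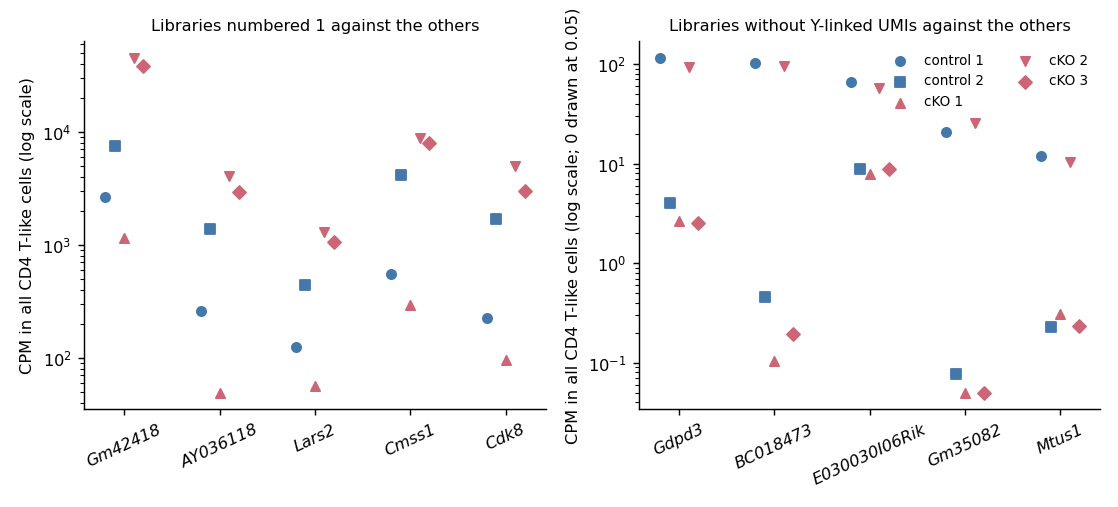
CPM per library in T-like cells of genes that part the libraries, on a log axis with values of 0 drawn at 0.05. Control 1 and cKO 2 are higher in Gdpd3, BC018473, E030030I06Rik, Gm35082 and Mtus1, and control 1 and cKO 1 lower in Gm42418, AY036118, Lars2, Cmss1 and Cdk8.

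In Treg-like cells, the genes of Treg identity and function had close means in both genotypes. Foxp3 (mm10, chromosome X, 7573644 to 7595245) was 113 ± 29.5 CPM (SD, n = 2) in controls and 106 ± 13.9 CPM (SD, n = 3) in cKO libraries, a log2 difference of -0.09 ± 0.18 (SE), which was -0.32 without control 1 and 0.21 without control 2. Ikzf2 had a log2 difference of -0.03, Il2ra, the high-affinity interleukin-2 receptor chain, -0.13, and the checkpoint receptor Ctla4 -0.18 (814 ± 188 and 717 ± 147 CPM). The suppressive cytokines Il10 and Tgfb1 gave 0.03 and 0.04. Of the sister receptors, Notch1 was -0.22 ± 0.15 (74.6 ± 16.1 and 63.9 ± 1.82 CPM) and Notch2 0.18 ± 0.11 (55.8 ± 0.201 and 63.3 ± 3.20 CPM), and the Notch target Dtx1 was 0.13. The Notch1 difference rested on control 2, at 86.0 CPM against 63.2 in control 1 and 61.8 to 65.4 in cKO libraries. None of these passed the test.

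Genes of other helper programmes did not pass in Treg-like cells either. The Th1 factor Tbx21 was 0.10 and its cytokine Ifng 0.63 ± 0.41 (5.91 ± 1.99 and 9.31 ± 4.19 CPM; 95% interval -0.31 to 1.56), and the Th2 and tissue Treg factor Gata3 was 0.06. The alarmin receptor Il1rl1 was -0.12, the repair factor Areg -0.02, the chemokine receptors Cxcr3 and Ccr6 0.01 and -0.16, the inhibitory receptors Pdcd1 and Lag3 -0.17 and 0.43 (95% interval of Lag3 -0.62 to 1.48), and Tnf -0.01. Notch3, the Notch target Hes1, the neuropeptide gene Npy and its receptor gene Npy1r, Il17a and Csf2 were too low to test. The plot of panel genes gives each log2 difference with its interval.

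**Figure D3:**
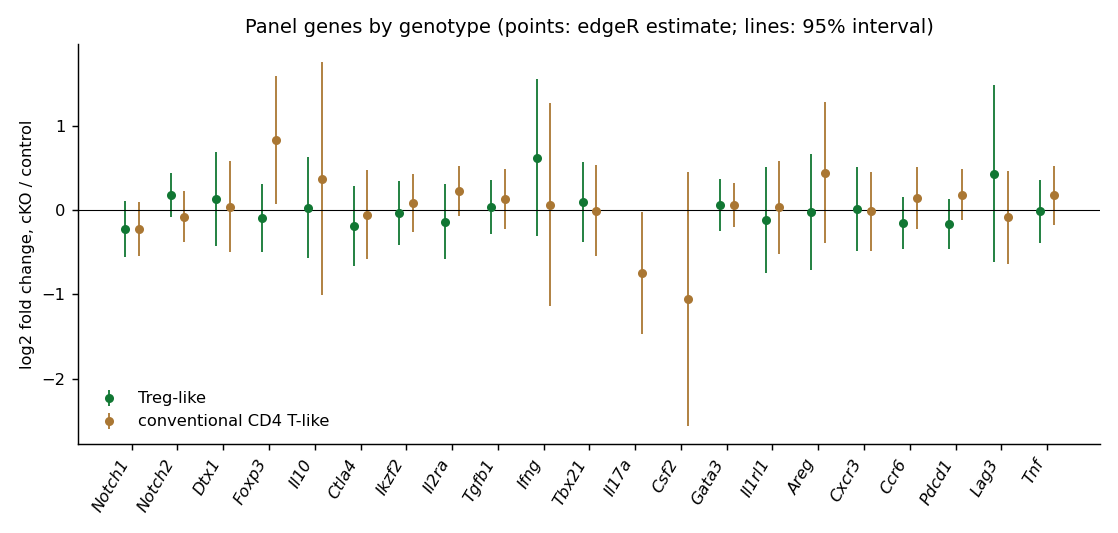
Log2 difference (cKO minus control) of panel genes in Treg-like and conventional CD4 T-like cells, with 95% intervals from the edgeR fit on 2 control and 3 cKO libraries. None passed the test, and the Treg-like interval of Foxp3 runs from -0.50 to 0.31.

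The 10 genes with the smallest p-values in Treg-like cells did not pass the test and are given as values. Of these, 9 were lower in cKO libraries, among them Rnaset2a, a lysosomal ribonuclease (-0.71 ± 0.13, 202 ± 3.33 to 124 ± 15.3 CPM), and its near-identical copy Rnaset2b (-0.75 ± 0.15), whose reads cannot be assigned to one copy with certainty. The same holds for the pseudogene Ftl1-ps1 (-1.31) and for Gm2000 (-0.99), a ribosomal protein gene copy. Irgm1, an interferon-induced GTPase, was -0.62 ± 0.14 (63.8 ± 3.73 and 41.5 ± 5.29 CPM), the death-associated kinase Dapk1 -0.91, the POU-domain factor Pou2f3 -1.34, the noncoding host gene Snhg5 -0.81 and the small GTPase Rab39 -1.15. Polr2l, a subunit of RNA polymerases, was higher, at 1.12 ± 0.25. Rnaset2a and Rnaset2b lie on chromosome 17, as Notch3 does, and an effect of position was not tested. Rnaset2a was also lower in conventional cells (-0.58), so its difference is not particular to cells in which the Cre is meant to act.

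Across 12487 genes tested in Treg-like cells, edgeR called 0, with 252 at an unadjusted p under 0.05, 122 higher and 130 lower, and a lowest adjusted p of 1.0. Without any effect a fraction of 0.05 of the tested genes would be expected there, more than these 252, so they are not read as signal. Other splits of the libraries gave 79 to 1520 such genes in Treg-like cells. DESeq2 called 1 gene by genotype, Rnaset2a, lower in cKO. In counts simulated at the means and estimated spread of these libraries, without their shared structure, edgeR recovered 93.1% of 2-fold and 32.2% of 1.5-fold changes. Only genes with a mean of at least 20 CPM were changed there. In the real libraries changes of 2-fold and those in lower genes could go uncalled too. Gm2000, at 162 ± 51.4 CPM in controls and 81.5 ± 15.1 CPM in cKO libraries, did not pass. With the library pairs and the low-Gm42418 libraries both as covariates, which leaves 1 degree of freedom, the count was 131, against 0 with either alone. In simulated data edgeR with this fit recovered 90.7% of 1.5-fold changes with 7.2 false calls per run. Those counts were drawn at a spread estimated from these same libraries, without their shared structure. They therefore cannot show whether the 131 calls are false, and these genes are left open.

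Of the lists of genes fixed in advance, camera at its preset correlation called 5 higher in Treg-like cells of cKO libraries, ribosomal proteins (64 of 70 measured members higher; adjusted p = 2.68e-09), heat shock and dissociation stress (28 of 35; adjusted p = 0.00197), oxidative phosphorylation (52 of 66; adjusted p = 0.00726), cytotoxicity (12 of 16; adjusted p = 0.0307) and glycolysis (17 of 21; adjusted p = 0.0307), and 1 lower, interferon gamma response (22 of 30 lower; adjusted p = 0.0159). For each of the 6 lists the adjusted p was 0.845 with an estimated correlation, and none of the calls held. Ribosomal proteins included Rpl35 (0.46), Rpl38 (0.38) and Rpl36 (0.34), stress genes the early genes Atf3 (1.74), Fosb (0.49) and Ier2 (0.24), and oxidative phosphorylation Atp5k (0.26) and Ndufb10 (0.21). Cytotoxicity genes included Nkg7 (0.46), Klrk1 (0.43) and Gzma (0.68), glycolysis the enolase Eno1 (0.71) and the hexokinase Hk2 (0.39), and interferon gamma response Irgm1 (-0.62) and the nonclassical class I gene H2-T23 (-0.64, 135 ± 33.4 and 86.8 ± 3.04 CPM). Those last 2 passed when adjusted over the list alone (lowest adjusted p = 0.0416), as 0 members of the other 5 called lists did, and over all genes 0 passed. H2-T23 lies on chromosome 17 (mm10, 36029773 to 36032855), as Notch3 does, and an effect of position was not tested. Without cKO library 1 the count of lists was 2. Of the 9 other splits of the libraries, 5 called at least 6 lists in Treg-like cells, up to 13, so this count is not particular to genotype. The members named as examples were chosen after their values were seen.

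The Notch pathway list did not pass in Treg-like cells (10 of 24 members higher, camera adjusted p = 0.935), with Maml3 at 0.19 and Aph1a at -0.17. Nor did Treg core (12 of 30 higher, adjusted p = 0.337), tissue Treg and repair genes (15 of 23, adjusted p = 0.211), Th1 (13 of 23, adjusted p = 0.266) or Th17 genes (9 of 18, adjusted p = 0.935). Type I interferon response genes were lower in 30 of 39 cases without passing (adjusted p = 0.134), and NF-kB and TNF response genes higher in 17 of 24 (adjusted p = 0.0903). Median, mean and test direction shared their sign for each called list, but not for the Hippo, Wnt, Th17, inhibitory receptor, CNS trafficking and MHC class II lists.

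**Figure D4:**
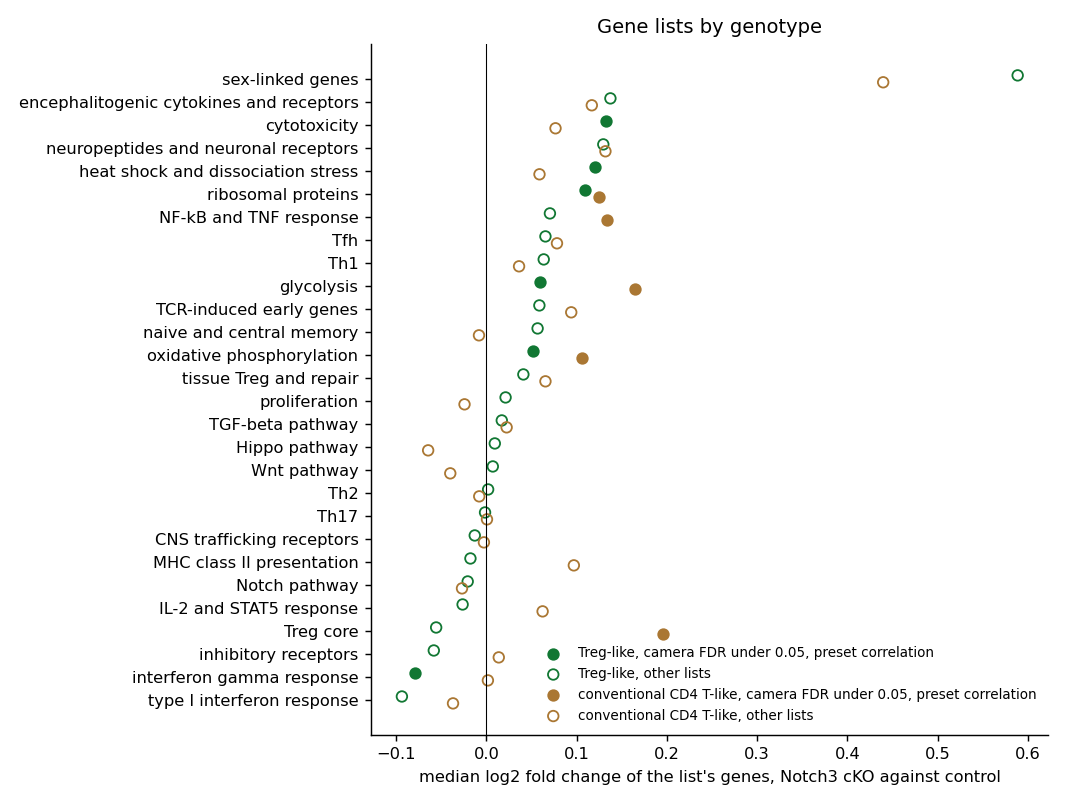
Median log2 difference (cKO minus control) of the members of each fixed list in Treg-like and conventional CD4 T-like cells, with filled marks for an adjusted camera p under 0.05 at the preset correlation. Ribosomal protein, oxidative phosphorylation and glycolysis lists lie to the right in both classes, and none of the filled marks holds with an estimated correlation.

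In conventional CD4 T-like cells, where the Foxp3-driven Cre is not meant to act, the cytokine gene Il17a was 29.8 ± 17.0 CPM (SD, n = 2) in controls and 17.7 ± 4.19 CPM (SD, n = 3) in cKO libraries, a log2 difference of -0.74 ± 0.32. It rested on control 1, at 41.8 CPM against 17.8 in control 2, and was -0.0143 without control 1, -1.23 without control 2 and 1.03 among cells with Xist and no Y UMIs. Csf2, the encephalitogenic cytokine GM-CSF, was 7.46 ± 6.77 and 3.48 ± 2.4 CPM (-1.05 ± 0.67), with 12.3 and 2.68 CPM in controls 1 and 2, and its difference turned to 0.393 without control 1. Ifng was 0.07 ± 0.54, Tnf 0.18 and Tbx21 -0.01. Foxp3, low in this class, was 2.77 ± 0.344 and 5.0 ± 1.13 CPM (0.83 ± 0.34). Il2ra was 0.23, Pdcd1 0.18, Areg 0.45, Ccr6 0.15, Il10 0.38, Tgfb1 0.13, Ikzf2 0.09, Notch1 -0.22 and Notch2 -0.08. Il17a and Foxp3 were under 0.05 in edgeR only before adjustment, and none of these genes passed the test.

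The 10 smallest p-values in conventional cells did not pass either. Among them, C1qa and Apoe, abundant in macrophages and microglia, were 2.65 and 1.19, and in all T-like cells C1qa was 1.13 ± 0.234 CPM (SD, n = 2) in controls and 2.53 ± 0.552 CPM (SD, n = 3) in cKO libraries, with Apoe at 4.86 ± 2.08 and 7.30 ± 0.777 CPM. Trp53inp2, an autophagy factor, was 1.16 and Dennd5b, a Rab exchange factor, 2.73. C77080 was -3.35, Rab39 -1.17, Wdr89 -0.81, and the genes with close copies Rnaset2a -0.58 and Gm2000 -1.06.

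Of 12487 genes tested in conventional CD4 T-like cells edgeR called 0, with 249 at an unadjusted p under 0.05, 127 higher and 122 lower. These 249 are also fewer than the fraction of 0.05 expected without any effect. DESeq2 called 1 gene, Gm2000. With the library pairs and the low-Gm42418 libraries as covariates the count was 105, and among the libraries with both sexes of cells (1 control, 2 cKO) it was 25.

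In conventional CD4 T-like cells of cKO libraries camera at its preset correlation called 5 fixed lists higher, ribosomal proteins (66 of 70; adjusted p = 1.30e-10), oxidative phosphorylation (58 of 66; adjusted p = 1.52e-07), glycolysis (20 of 21; adjusted p = 0.000194), NF-kB and TNF response (21 of 24; adjusted p = 0.00023) and Treg core (24 of 30; adjusted p = 0.000444). For each of these 5 lists the adjusted p was 0.693 with an estimated correlation, and 0 members passed over all genes or adjusted over the list alone. Of the 9 other splits of the libraries, 6 called at least 5 lists in conventional cells, up to 13, so this count is not particular to genotype. Members were Rpl35 (0.52) and Rpl38 (0.39), Atp5k (0.40) and Ndufv1 (0.37), Eno1 (0.74), and of the NF-kB list Bcl2a1b, a survival factor (0.37 ± 0.12), Nfkb2 (0.34) and Nfkbie (0.31). Members of the Treg core list were Foxp3 (0.83), Gpr83 (0.78), Il2ra (0.23) and the costimulatory receptor Tnfrsf4 (0.22). The count of lists was 8 without control library 1, 2 without cKO 1, 10 without cKO 2 and 9 without cKO 3.

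Lists of pathogenic helper programmes did not pass in conventional CD4 T-like cells. Th17 genes were higher in 11 of 22 cases (adjusted p = 0.75), with Il17f at 0.41 and Aqp3 at -0.37, Th1 genes in 14 of 24 (adjusted p = 0.161), and encephalitogenic cytokines and receptors in 12 of 17 (adjusted p = 0.161), with Il2 at 0.89 and Ccl1 at 0.71. The Notch pathway list was higher in 9 of 25 (adjusted p = 0.772). Signs of median, mean and test differed for the Th17, Th2, type I interferon, interferon gamma, CNS trafficking and proliferation lists.

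Summed over all CD4 T-like cells, the smallest p-values went to Rnaset2a (-0.63 ± 0.12), Rab39 (-1.12 ± 0.22), Cnot6, a deadenylase subunit (-0.45 ± 0.10, 132 ± 2.45 and 96.9 ± 6.78 CPM), and Sostdc1, a secreted antagonist of BMP and Wnt signals that was near 0 in both groups (0.0391 ± 0.0552 and 0.982 ± 0.241 CPM). The rest of these 10 were Gm2000, C77080, Ftl1-ps1, Phpt1, Dapk1 and Pou2f3, all lower in cKO libraries. Il17a was -0.71, under 0.05 only before adjustment, Csf2 -1.0, Notch1 -0.17, Ctla4 -0.20 and Foxp3 -0.02. Of 14190 genes edgeR called 0, with 242 at an unadjusted p under 0.05 (103 higher, 139 lower). Those 242 are fewer than the fraction of 0.05 expected without any effect. DESeq2 called 2, Rnaset2a and Gm2000, both lower. With both library contrasts as covariates the count was 244.

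In all CD4 T-like cells camera at its preset correlation called proliferation genes lower (30 of 40 lower; adjusted p = 0.0141) and 5 lists higher, ribosomal proteins (66 of 70; adjusted p = 2.74e-13), oxidative phosphorylation (61 of 66; 1.68e-07), glycolysis (20 of 22; 0.00236), NF-kB and TNF response (19 of 24; 0.00392) and heat shock and dissociation stress (26 of 35; 0.00914). For each of the 6 the adjusted p was 0.964 with an estimated correlation, and 0 members passed over all genes or adjusted over the list alone. Of the proliferation genes the helicase subunit Mcm7 was -0.38, the tubulin Tuba1b -0.27 and the topoisomerase Top2a -0.46, while the shares of cycling cells had close means in the 2 groups. Without cKO library 1 the count of lists was 3. Signs of median, mean and test differed for the Hippo, Wnt, encephalitogenic, Th2, naive and central memory, IL-2 and STAT5, and CNS trafficking lists.

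To ask whether the genotype acted differently in Treg-like and conventional cells, the difference of the effects was tested within libraries. Hbb-bs, a haemoglobin chain of red cells, was the 1 gene of 13050 called (log2 6.95 ± 0.69, edgeR adjusted p = 0.000317), and 1132 of its 1143 UMIs in Treg-like cells of cKO library 3 lay in 1 cell. The reads of Hbb-bs, Hba-a1 and their close copies cannot be assigned to one copy with certainty. The count was 18 without control library 1, 2 without cKO 1, 3 without cKO 2, 0 without cKO 3, and 78 in the libraries with both sexes of cells. At an unadjusted p under 0.05 there were 638 genes, 347 higher and 291 lower, and DESeq2 called 0. A fraction of 0.05 of the tested genes, about as many, would be expected without any effect. Next by p came 4933406I18Rik (0.73), Hba-a1 (6.63), the trefoil peptide Tff1 (-2.81), the chemokine Ccl4 (-2.54), Rab30 (2.61), Gramd3 (0.41), Arhgap24 (2.73), Trim67 and Atp8b4 (0.74), none past the threshold. Among panel genes, Foxp3 was -0.93 ± 0.26 (edgeR adjusted p = 0.836), Pdcd1 -0.35 ± 0.12, Il2ra -0.35 ± 0.13, Ccr6 -0.30 and Notch2 0.25, again not past it. Over the alternatives 14 of 22 panel genes turned direction at least once here, 17 of 20 in Treg-like and 20 of 22 in conventional cells. No panel value passed in Treg-like cells under any alternative, while a few did in the other comparisons.

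By lists at the preset correlation, the difference of effects was called lower in Treg-like relative to conventional cells for Treg core (26 of 30 members lower; camera adjusted p = 3.55e-07), interferon gamma response (24 of 30; adjusted p = 0.00113) and oxidative phosphorylation genes (54 of 66; adjusted p = 0.00393). The adjusted p was 0.804 with an estimated correlation for all 3 interaction lists, and 0 members passed over all genes or adjusted over the list alone. Each of the 9 other splits of the libraries called at least 3 lists, up to 8, so this count is not particular to genotype. Members of Treg core were Foxp3 (-0.93), the integrin Itgae (-0.62), Il2ra (-0.35) and Capg (-0.22), those of the other pair Gbp2 (-0.21) and H2-T23 (-0.17), and Ndufa8 (-0.22) and Uqcr11 (-0.20). The count of lists was 8 without control library 1 and 5 without control library 2. Signs of median, mean and test differed in this comparison for the Notch, Hippo, tissue Treg, Th1, Tfh, early TCR, CNS trafficking and sex-linked lists.

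The share of cells with at least 1 UMI was compared after thinning each cell to 2000 UMIs. In Treg-like cells 7 of 26 panel genes were fully apart, all with lower shares in cKO libraries, where chance parts 20%. Among them, Notch1 was seen in 14.0% ± 3.54 (SD, n = 2) of control and 10.7% ± 0.402 (SD, n = 3) of cKO cells (exact permutation p = 0.1), Ccr6 in 6.34% and 5.48%, Tnf in 3.73% and 3.15% and Il10 in 1.02% and 0.685%, with Il17a and Csf2 near 0. The lowest adjusted p was 0.52, and without thinning 1 gene was apart, Hes1, with Notch1 in 26.8% and 26%, Ccr6 in 12% and 12.2%, Tnf in 8.06% and 8.05% and Il10 in 2.13% and 2.29% of cells. Without control 1 the count of genes apart was 14, and without control 2 it was 13. With 1 control left chance parts the groups in 2 of 4 splits, so these counts are not read as an excess. Dendritic-like cells, the reference for free RNA, gave Notch1 in 11.8% of 93 cells thinned alike, Ccr6 in 2.15%, Tnf in 4.30% and Il10 in 0 (up to 3.23%). Unthinned, Cd3e was in 42% and Foxp3 in 14% of that cluster, and dendritic cells can make Notch1 and Tnf themselves, so for Notch1, Tnf and Il10 background was not told apart from expression. Median depths were 3375 to 4779 UMIs per library in Treg-like and 4736.5 to 10526.5 in dendritic-like cells.

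Foxp3 was seen in 19.2% ± 2.15 (SD, n = 2) and 17.5% ± 1.90 (SD, n = 3) of thinned Treg-like cells of control and cKO libraries, against 1.08% of dendritic-like cells, and in 33.7% and 35.9% unthinned. Ctla4 was seen in 68.5% and 64.9% against 22.6%, and Il2ra in 43.0% and 40.5% against 11.8%. In conventional CD4 T-like cells 3 of 26 genes were apart. Notch2 was in 10.2% and 8.73% of cells and Il17a in 1.05% ± 0.0488 (SD, n = 2) and 0.754% ± 0.145 (SD, n = 3), both lower in cKO libraries, and Areg in 0.504% and 0.731%. Each adjusted exact permutation p was 1, and in dendritic-like cells Notch2 was in 19.4%, Il17a in 0 (up to 3.23%) and Areg in 3.23%. Unthinned, 4 genes were apart, all with higher shares in cKO libraries, Foxp3 (1.03% and 1.68%), Areg (0.885% and 1.27%), Ccr6 (6.60% and 7.28%) and Pdcd1 (9.51% and 11.6%), with each adjusted exact permutation p at 1, while Notch2 was in 18.2% and 17.9% and Il17a in 1.54% and 1.42%. The count of genes apart was 10 without control 1 or cKO 1, 8 without control 2 and 6 without cKO 2. Chance parts the groups in 2 of 4 splits with 1 control left, and in 2 of 6 with 2 cKO libraries left.

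Other classes with at least 20 cells in every library were tested cluster by cluster. In the cycling T-like, innate-like T-like, macrophage mixture and unnamed T-like clusters, the last led by Ifitm1, Ifitm3 and Lgals3, by Eomes and Gzmk, or by Ifit3 and Isg15, edgeR called 0 genes each, with 142 to 343 at an unadjusted p under 0.05, and DESeq2 called 0. Without cKO library 1 there were 34 calls over these clusters, among them Gm42418, Lars2 and Camk1d, without control 1 there were 14, without cKO 2 there were 9 and without control 2 there were 5. Tested 1 by 1, the Treg-like and conventional clusters had 0 calls in edgeR, with 182 to 304 genes at an unadjusted p under 0.05, except cluster 0, where Gm49180, an unstudied predicted gene, was called higher. With all libraries kept, the genes at an unadjusted p under 0.05 were in every cluster fewer than the fraction of 0.05 expected without any effect.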

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

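The tests of Hbb-bs, of the gene lists and of the Treg-like share were planned. So were the alternatives of resolution, of a left-out library and of equal cells and UMIs. The look at single cells, leaving out a cluster and the tests of explanations for the patterns below were chosen after the results were seen. Hbb-bs had a genotype effect of 6.95 (log2, adjusted p = 0.000317) in Treg-like relative to conventional cells. In cKO library 3 Treg-like cells held 1143 of its UMIs, 1132 of them in 1 cell, and conventional cells 8. Control library 2 held 16 and 17, and the other 3 libraries 0. Without Notch3 cKO replicate 3 the comparison called 0 genes, and at resolution 0.5 and 2 it called 0 as well.

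Control 1 and cKO 2 differ from the other 3 libraries in autosomal genes such as Gdpd3, Pde4d, St6galnac1 and Mtus1. Sex of the pooled cells is argued against as the whole cause, since among cells with Xist and no Y UMIs the log2 differences had a median ratio of 1.05 to those in all T-like cells (quartiles 0.971 and 1.16). At equal cells and UMIs per library the median ratio was 1.01 (quartiles 0.977 and 1.04). Thinning the sums keeps each gene's expected CPM, so that ratio cannot decide whether a difference in depth plays a part. Variants of the genetic background may contribute: 12 of the 50 called autosomal genes lie within 1 Mb of another, where random draws gave a median of 4 and a 95% point of 9. The draws were not matched for expression or for related neighbouring genes, so this excess is not particular to variants. Separate days, litters or animals were not tested and stay open, as the labels give none of them.

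Treg core genes were called higher in conventional CD4 T-like cells of cKO libraries at the preset correlation, with an adjusted p = 0.693 at an estimated correlation. Treg-like cells or their RNA in that class may be part of it. Over 29 members without Foxp3, those with a higher Treg-like to conventional ratio had higher fold changes (Spearman rho 0.473, permutation p = 0.0103), but the 2.01% of mixing that Foxp3 would need predicts a median of 0.09, against 0.17 observed. Genes of the list moving together between libraries may be another part, since 3 of the 9 other splits also gave the list an adjusted p under 0.05 in conventional cells and 4 in the interaction. A genuine change of state in these cells stays open and was not tested apart from these.

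The high-UMI Treg-like cluster 10 may hold pairs of cells under 1 barcode. In the libraries with both sexes, 40.3% (36.2% to 44.6%) of its cells with either sign carried both Xist and Y-linked UMIs, where 49.6% would be expected if all were pairs, and 4.18% of other cells did. More RNA per cell alone is argued against, since its cells and cells outside it, matched 1 to 1 in UMIs and library (523 of each, median 10515 and 10509 UMIs), carried both in 209 (35.9% to 44.2%) and 114 cases (21.8%, 18.5% to 25.5%). Without this cluster edgeR called 0 genes in Treg-like cells, and the Treg-like share differed by -2.58 points with the groups fully apart (exact permutation p = 0.2), against -1.66 points with the groups overlapping when the cluster is kept.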

How the results depend on the processing

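Covariates for the library pair and the number 1 libraries, mixed-sex libraries alone, Xist-bearing cells alone and leaving out clusters were chosen after the results were seen. Causes named below were not tested unless stated. For Treg-like genes 18 of 22 alternatives gave the same count of 0 in edgeR, for conventional cells 19 of 23 and for all CD4 T-like cells 18 of 20. DESeq2 called 1, 1 and 2 genes, and no low-count filter gave 71 in Treg-like and 69 in conventional cells. Mixed-sex libraries alone gave 1 and 25, where the control arm has 1 library that is assumed to vary like the other group. Both covariates together gave 131, 105 and 244 at 1 residual degree of freedom. Leaving out any 1 library gave 0 to 0 in each.

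The interaction kept its count in 5 of 18 alternatives: it was 0 with DESeq2, at resolution 0.5 and 2 and with doublets kept, 2 with equal cells and UMIs, 8 with the library set as a covariate, 22 without a filter, 37 with both covariates and 78 in mixed-sex libraries. Leaving out 1 library gave 0 to 18, with 18 without control 1, 2 without cKO 1, 3 without cKO 2 and 0 without cKO 3. Other classes gave 172 genes without a filter and 0 to 34 leaving out 1 library. Without 1 control the lone control is assumed to vary like the cKO libraries.

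Replicate block: pairing by number gave 0 genes in Treg-like, conventional and all CD4 T-like cells, and 7, 8 and 8 lists. The paired libraries of the same number correlated at 0.0987 and -0.136 in Treg-like cells. With 2 controls centred on their mean, a cKO library correlates with them at equal size and opposite sign. For cKO 2 it was 0.136 with control 1, so these values cannot check the pairing. In this fit cKO 3 has no control of its number and adds nothing to the genotype effect. Control 1 and cKO 1 share low Gm42418 counts and 36 called genes in Treg-like cells, so a step shared by the number 1 libraries stays open.

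The Treg-like share difference of -1.66 points was -2.48 at resolution 0.5, -3.27 at resolution 2 and -2.18 with the strict filter, with the groups apart in each, -0.949 with the loose filter, where the shares fell from 36.3% and 34.6% to 22.97% and 22.02%, and -1.41 with doublets kept, with the groups not apart in either, -3.0 to -0.323 leaving out 1 library and 0.565 by a Foxp3 UMI. Classes parted were 1 at resolution 0.5, 1 with the loose and 2 with the strict filter, and 0 to 7 leaving out 1 library. UMI shares parted 1 Treg-like and 4 conventional genes unthinned, and 9 to 14 leaving out 1 library, 4 to 10 in conventional cells. With 1 library left out chance parts the groups more often than the 20% of the full set, so these ranges are not read as an excess. The Notch3 difference in Treg-like cells, 0.0853 CPM and 0.0606 to 0.128 leaving out 1 library, rests on 2 UMIs and lies under the 0.584 and 0.686 CPM that counts of 0 allow in the controls, so it was not detectable at this depth.

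All list counts by genotype were 0 with an estimated correlation and 0 with fry. Leaving out 1 library gave 2 to 9 in Treg-like, 2 to 10 in conventional, 3 to 8 in all CD4 T-like cells and 2 to 8 in the interaction. The library set as a covariate gave 3 Treg-like, 8 conventional and 6 interaction lists, both covariates 10 conventional and 8 interaction lists, and leaving out cluster 7, at 0.804 of its library medians in UMIs, gave 10 in conventional cells.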

Other observations

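The comparison of cells by sex and all other tests in this part were chosen after the data were seen. In the 3 libraries with both sexes, conventional CD4 T-like cells with Y-linked UMIs had more of the naive and memory genes Igfbp4 (log2 2.17) and Dapl1 (1.17), and of St8sia6 (2.26), a sialyltransferase, Cpm (2.04) and Tox (0.78), an exhaustion factor. Cells with Xist had more of Ly6c2, a member of the Th1 list (-1.66, 76.0 ± 18.3 CPM in Y-bearing and 243 ± 11.2 in Xist-bearing cells, SD, n = 3). They also had more of the cytotoxicity genes Gzma (-1.05) and Klrc1 (-0.87), and of Nrgn (-2.02), Lgals3 (-1.33) and Ifitm3 (-1.18). Named genes were required to have the same direction in all 3 libraries. Between 3000 and 8000 UMIs edgeR called 666 genes, 319 higher in Y-bearing and 347 in Xist-bearing cells, 637 of them autosomal.

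By lists, conventional CD4 T-like cells with Y-linked UMIs had naive and central memory genes higher (17 of 18, 9 called; camera adjusted p = 1.81e-17), and Th1 (18 of 22 lower, 11 called; 5.07e-16), cytotoxicity (12 of 15 lower, 7 called; 1.47e-09) and ribosomal protein genes lower (67 of 70, 58 called; 2.40e-79). With an estimated correlation the adjusted p was 0.162, 0.162, 0.196 and 0.361, and with fry it was 0.0106, 0.000999, 0.0122 and 0.0759, so fry kept 3 of the 4 lists. Adjusted over the list alone, 11, 15, 8 and 61 members passed. Y-bearing and Xist-bearing cells lay in different clusters, so these list and gene differences can follow the make-up of the class. Within conventional clusters 0, 1 and 6 edgeR called 85, 143 and 135 autosomal genes, and clusters 3, 7 and 9 were not tested alone.

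In Treg-like cells edgeR called 385 genes by sex at all depths, 187 higher in Y-bearing and 198 in Xist-bearing cells. Between 3000 and 8000 UMIs it called 242, 130 higher in Y-bearing cells, such as the chemokine receptors Ccr4 (0.78) and Ccr2 (0.72), Tlr1 (0.99) and Cycs (0.85), and 112 higher in Xist-bearing cells, such as the leukotriene receptor Ltb4r1 (-1.23), Ston1 (-1.25) and the potassium channel Kcnq5 (-0.92). Treg-like cells were 37.0% ± 2.32 (SD, n = 3) of Y-bearing and 29.9% ± 1.11 (SD, n = 3) of Xist-bearing T-like cells, higher in 3 of 3 libraries. Cluster 2, with Ifitm and Lgals3, was 4.90% and 13.0%, cluster 3, with Ccr7, 7.17% and 3.08%, and cluster 9, with Ifng, 2.17% and 5.39%. In control 1 and cKO 2, Xist-bearing T-like cells were 38.8% and 37.0% Treg-like, within the Y-bearing range of 35.2% to 39.6%. Cluster 2 was 6.38% and 6.26% of them, nearer the Y-bearing share. Cluster 3, at 4.02% and 3.51%, was nearer the Xist-bearing share, and cluster 9, at 4.22% and 4.27%, lay between. The Treg-like and cluster 2 differences thus did not extend to Xist-bearing cells of that pair. Cells must carry an Xist or Y-linked UMI to be counted, so detection enters. As a control, cells with and without a Xist UMI were compared in the same way in the libraries without Y-bearing cells, which called 276 genes in Treg-like and 405 in conventional cells, 60 and 128 of them among the 367 and 706 autosomal genes called by sex at all depths. In conventional cells the log2 differences of the called autosomal genes correlated with this control (Spearman 0.483 over 689 genes), in Treg-like cells at -0.102 over 363. Cells without less cells with a Xist UMI differed by -2.44 points in cluster 2, 6.49 in cluster 3, -3.11 in cluster 9 and -5.99 in the Treg-like share. This control thus gave as much as was seen by sex in cluster 3 and nearly as much in cluster 9. For the Treg-like share it went the other way, against 7.02 points by sex. Both arms of the sex comparison carry a UMI, unlike this control, so it cannot size what detection adds there. Sex, and any difference between the pooled animals, are the same split here.

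Cluster 15 held 76 cells with genes of CD4 and CD8 double-positive thymocytes: Rag1, the antigen receptor recombinase, in 80.3% of cells, the terminal transferase Dntt in 75.0%, Arpp21 in 88.2%, Cd8b1 in 98.7%, Cd4 in 76.3% and Ccr9 in 84.2%. Control 1 had 25 (0.911%, 0.618% to 1.34%) and cKO 2 had 51 (0.966%, 0.735% to 1.27%), the pair that also differs in autosomal genes. The other libraries had 0 of 3558, 3185 and 5259 cells, which allows up to 0.0843%, 0.0942% and 0.0570%. Notch3 was in 3 of the 76 cells (3.95%, 1.35% to 11.0%) and in 0.0211% of T-like cells, at median depths of 2510.5 and 4083 UMIs.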
